A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

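RNA of 10 to 40 nucleotides was purified from total RNA on a gel or with a fractionating device and made into small RNA libraries for Illumina sequencing, per the labels' protocols. There was 1 library for each of 4 genotypes, and genotypes were taken from the labels. The submitters' processing notes name cutadapt, an adapter trimmer, and Bowtie, a short-read aligner. Their versions, the genome build, the annotation, the treatment of strand and of reads that map to several places, and the rule by which libraries were scaled are not given in the sources used here. Molecular identifiers are not mentioned in them, so reads are not known to be independent molecules, and every interval covers counting error alone.

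The deposited table gives 1 value per gene and library. The WT column holds a whole-number count of reads per gene as deposited. The other 3 columns hold a deposited signal per gene that equals whole reads multiplied by 1 factor per library: 100% of the values in each column were whole multiples of the smallest non-zero value, to a tolerance of 1e-06. The reads were recovered by dividing by that value, and values were not divided by gene length. The design fixed before the data were examined foresaw values scaled to a common total if the table held counts; as only 1 column did, the deposited scale was kept and division by each library's sum was run as an alternative.

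Of the identifiers, 5789 matched the RefSeq annotation of assembly R64, which was used for gene symbols, products, overlaps, neighbours and coding lengths. Overlaps and distances therefore rest on its coordinates, while the build of the deposited table is not known. The 9 unmatched identifiers are named as the table gives them. Transcript classes other than listed genes, such as XUT, SUT and CUT transcripts, tRNAs and snoRNAs, were not analysed here. Lists for Ty elements and Ty reading frames found 0 genes; a first version of the product search for the second list had taken GAG1, which is no Ty gene, and was corrected after its values were seen. Of 24 seripauperin genes 16 had 0 reads in every library, and of 8 subtelomeric helicase genes 6, so that neither list was described. The symbol patterns also took RPP1 into the ribosomal protein list, COS111 into the COS list and MRP8 into the mitochondrial ribosomal protein list, and the lists were kept as fixed. FLO, COS, hexose transporter, histone and ribosomal protein genes have near-identical copies, so their values are uncertain where reads could map to more than 1 copy.

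Differences are of log2(value + 3.18), where the pseudocount is the 10th percentile of the non-zero values over the 4 libraries. This understates the change of genes with low values, and folds quoted for single genes are plain ratios of values with an exact Clopper-Pearson interval. Where a count was 0, folds given as at least divide the higher value by that of 3 reads. They leave out counting error in the higher value, so they are not 95% limits. A gene was counted in a comparison where 1 of its libraries reached the pseudocount, and as higher or lower at a log2 difference of 1 or more in size. No test across libraries was run for the comparisons. A list's median is given relative to the median of the 5767 nuclear coding genes, with its percentile among 10000 random lists of the same size matched on mean log2 value in 20 bins, as a description of these libraries. Genes were named by a rule fixed with the design: XRN1, the 10 highest and 10 lowest differences per comparison among genes of value 31.8 or more in the higher library, the 10 highest values in xrn1 RNAi, the 3 members of each list with the largest difference, and 8 antisense pairs. Other settings chosen with that rule were a pseudocount of 0.318 or of 31.8, no filter, a filter at 10 times the pseudocount, division by the sum of each library, size factors (median of ratios over coding genes above 0 in every library), and an antisense overlap of 200 or 1 bases.

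Because reads could be recovered, a quasi-likelihood test of an additive model (DCR1 and AGO1, XRN1 deletion) was added with edgeR 4.0.16 in R 4.3.3 after the data were seen. It has 1 residual degree of freedom and uses the 2 backgrounds as replicates of each effect. Counting, list percentiles and edgeR were tested on simulated data for 5539 genes with 200 changed 8-fold. For RNAi over WT, counting recovered 198 of the 200 with counting error alone, and 19 of 5339 unchanged genes passed 2-fold; with an added dispersion of 0.1 it recovered 196, and 662 unchanged genes, 12.4%, passed. The edgeR fit of the effect of DCR1 and AGO1 recovered 193 and called 8 unchanged genes at a dispersion of 0.1; at 0.254, the dispersion fitted to the real data, it recovered 36 of the 200 and called 0. Counting was not simulated at 0.254, so the 12.4% is not the share of unchanged genes that would pass 2-fold in the real data. Of 200 unchanged lists of 20 genes, simulated at 0.1, 8 lay outside the central 95% of random lists. Other computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.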

Results

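Small RNAs of Saccharomyces cerevisiae, the budding yeast, were sequenced from 4 genotypes, with 1 library each. Budding yeast lacks RNA interference (RNAi), and the pathway can be rebuilt in it by adding DCR1, which encodes a Dicer enzyme that cuts double-stranded RNA into small RNAs, and AGO1, which encodes the Argonaute protein that binds them. The libraries came from wild-type cells (WT), from cells with DCR1 and AGO1 (RNAi), from cells lacking XRN1 (xrn1), the cytoplasmic 5′ to 3′ exoribonuclease, and from cells lacking XRN1 that also carried DCR1 and AGO1 (xrn1 RNAi). The series title gives the purpose as the mapping of double-stranded RNA with the rebuilt pathway. The reads over the listed genes numbered 627607 in WT, 1801407 in RNAi, 2825322 in xrn1 and 7686801 in xrn1 RNAi. Values below are on the deposited scale, on which 1 read was worth 1 in WT, 0.318 in RNAi, 0.330 in xrn1 and 0.0762 in xrn1 RNAi. With 1 library per genotype no difference has a replicate check, no p-value is given across genes for the comparisons, and intervals are 95% intervals of counting error alone. Words such as rose and fell describe the difference between 2 libraries. Since scaling moves every gene of a library together, list medians are given relative to the median of nuclear genes. With size factors these relative medians kept their sign in the 4 comparisons, except that of RNA decay genes in xrn1 RNAi over RNAi. That is little of a check, since 1 factor per library changes a relative median only through the pseudocount. Counts of higher and lower list members are on the deposited scale.

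XRN1 (YGL173C), the deleted gene, had a value of 148 (Poisson interval 125 to 174) in WT and 12.4 (8.81 to 16.9, 39 reads) in RNAi. It had 3 reads in xrn1, a value of 0.991 (0.204 to 2.90), and 0 reads in xrn1 RNAi, where a count of 0 allows up to 3 reads or a value of 0.229. The value in xrn1 was 149-fold below that in WT (interval 50.1 to 732), and the value in xrn1 RNAi was at least 54.2-fold below that in RNAi.

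**Figure D1:**
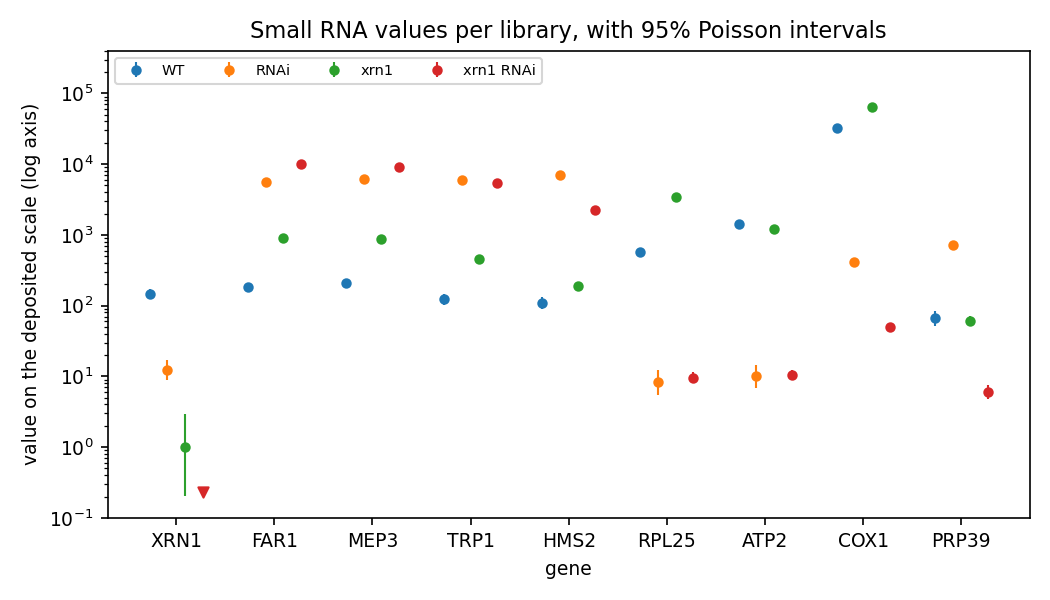
Values of 9 named genes in each of the 4 libraries on the deposited scale (log axis), with 95% Poisson intervals as bars; the triangle marks the 3 reads that a count of 0 allows. FAR1, MEP3, TRP1 and HMS2 were higher in both libraries with DCR1 and AGO1, RPL25, ATP2 and COX1 were lower in both, and PRP39 was 716 in RNAi against 6.02 in xrn1 RNAi.

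Addition of DCR1 and AGO1 to cells with XRN1 (RNAi over WT) addressed which genes had more small RNA with the rebuilt pathway present. Read lengths were not examined, so a higher value is not shown to be a product of the pathway. HMS2 (YJR147W), a gene for a protein similar to heat shock transcription factors, rose from 110 to 6918, a 62.9-fold difference (interval 52.2 to 76.6). TRP1 (YDR007W), a tryptophan synthesis gene, rose from 123 to 5964 (48.5-fold, 40.6 to 58.4), and PDR3 (YBL005W), a transcription factor gene of multidrug resistance, from 193 to 7073 (36.6-fold, 31.8 to 42.4). The other genes with the highest differences were the cell wall gene HPF1 (48.9-fold), PET122 (46.6-fold), the flocculin gene FLO1 (68.9-fold, from 5 reads in WT), UIP5 (43.8-fold), the transporter gene MCH5 (42.0-fold), the glyoxylate cycle gene ICL1 (42.2-fold) and SGF29 (36.6-fold). FLO1 has close paralogs, and reads shared with them cannot be told apart here. In the opposite direction, ATP2 (YJR121W), a mitochondrial ATP synthase gene of the nuclear genome, fell from 1446 to 10.2 (142-fold, interval 100 to 209) and BAT1, an amino acid aminotransferase gene, from 773 to 5.40 (143-fold, 88.8 to 247). The lowest differences were those of 4 identifiers that the reference does not match, R0010W (4351 to 0.318, 1 read, 13701-fold with an interval of 2458 to 541267), R0020C (2231 to 0 reads, at least 2342-fold), R0040C (1620 to 0 reads, at least 1700-fold) and R0030W (577 to 0 reads, at least 606-fold). The naming scheme gives such identifiers to the 2-micron plasmid, and whether the strains with DCR1 and AGO1 carried it is not given in the sources used here.

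Genes of the mitochondrial genome made up 26.7% of the reads over genes in WT (Clopper-Pearson interval 26.6 to 26.8%) and 0.361% in RNAi (0.353 to 0.370%). All 19 were 2-fold or more lower in RNAi, and COX1, a cytochrome oxidase subunit gene, went from 32851 to 407. The introns AI1, AI2, AI3 and AI4, listed as genes, lie within COX1, so their reads are counted repeatedly; without the 9 nested features the shares were 10.0% and 0.120%. Ribosomal protein genes were 2-fold or more lower in 129 of 135 counted members and higher in 1, RPP1, which encodes a subunit of RNase P and entered the list by its symbol. RPL25 fell from 568 to 8.26. The ribosomal protein median log2 difference was -3.24, which was -1.68 relative to the median of nuclear genes (-1.56) and lower than in all of 10000 random lists matched on mean value (percentile 0).

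Galactose genes had a relative median of 2.64, at percentile 95.7. Of the 7 counted, 4 were higher and 2 lower: GAL1, the galactokinase gene, rose from 84 to 1607 and the repressor gene GAL80 from 50 to 905, while GAL2, the permease gene, fell from 31 to 3.49. Of 20 meiosis genes 2 were higher and 9 lower, with a relative median of 0.87 at percentile 99.8. The kinase gene SMK1 rose from 21 to 826 and the septin gene SPR3 fell from 77 to 0.635, which is 2 reads. Phosphate genes were split as well, with 4 higher and 2 lower of 11: PHO5, an acid phosphatase gene, rose from 34 to 517 and PHO81, a regulator of the pathway, fell from 512 to 21.6. Genes of the COS list were higher in 5 and lower in 1 of 7 (relative median 2.64, percentile 99.9), mostly at low values, such as those of COS6 (3 to 15.6) and COS7 (0 to 8.26). Among those higher was COS111 (50 to 119), which entered the list by its symbol. COS1, COS6 and COS7 were below the pseudocount in WT, so they could not be counted as lower. Heat shock genes were lower in 9 and higher in 1 of 12, among them HSP78 (153 to 3.49, with 11 reads in RNAi). RNA decay genes were lower in 13 and higher in 2 of 21, among them DCP2, the decapping enzyme gene (114 to 6.03). Histone genes were lower in 7 of 8, including HTB1 (17 to 0.635, 2 reads). Glycolysis genes were higher in 3 and lower in 5 of 17: ADH1, an alcohol dehydrogenase gene, rose from 231 to 3388, and FBA1, the aldolase gene, fell from 480 to 13.0. Mitochondrial ribosomal protein genes were lower in 42 and higher in 3 of 55, mating genes lower in 4 and higher in 1 of 8, and hexose transporter genes lower in 3 and higher in 1 of 9. The mating pheromone gene MF(ALPHA)2 rose from 47 to 345 and MF(ALPHA)1 fell from 49 to 0.953, which is 3 reads. Apart from the COS genes, the lists from the phosphate genes on lay between percentiles 11.8 and 90.5. Intervals of the relative medians were -0.87 to 5.77 for galactose, -0.12 to 1.85 for meiosis and -0.10 to 3.41 for COS genes. Each reached below the nuclear median, so the direction of these 3 lists is uncertain. With a pseudocount of 31.8 in place of 3.18, the relative medians above were -0.91 for ribosomal protein, 1.29 for galactose, 0.39 for meiosis and 0.93 for COS genes, and with only genes of value 31.8 or more that of meiosis genes was 1.95.

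Across all genes, 833 were 2-fold or more higher and 3303 lower in RNAi than in WT, of 5479 counted. With size factors, which shift RNAi against WT by 1.92 on the log2 scale, 1911 were higher and 1833 lower, and with a pseudocount of 31.8 the number lower was 1898. ATP2, FBA1, RPL25 and COX1 were lower and HMS2, TRP1, PDR3 and GAL1 higher with that scaling too.

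The same addition in cells lacking XRN1 (xrn1 RNAi over xrn1) raised many of the same genes. FAR1, which encodes an inhibitor of the cell cycle in mating, had the highest value of the library, 10138, against 916 in xrn1 (11.1-fold, interval 10.7 to 11.5). It was followed by the ammonium permease gene MEP3 (8976), MCH5 (8057) and TAT1 (7825), an amino acid permease gene; APE1, TRP1, PDR3, ADH1, the purine permease gene FCY2 and the ammonium permease gene MEP1 completed the 10 highest. The highest differences were those of HPF1 (231 to 3131, 13.6-fold), the thiamine transporter-like gene THI72 (24.1 to 352), CTA1, the peroxisomal catalase gene (69.7 to 935), AIM33 (104 to 1377), MBR1, SFK1, FLO5, RSB1, ICL1 and PDR3. Beyond the mitochondrial genome, RPL25 fell from 3431 to 9.60 (357-fold, 300 to 429) and RPL10 from 2386 to 12.3 (194-fold, 166 to 229).

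Mitochondrial genes took 33.1% of the reads in xrn1 and 0.0394% in xrn1 RNAi, or 13.4% and 0.0154% without the nested features. COX1 went from 63612 to 49.2 (1292-fold, 1196 to 1398), and COB, the cytochrome b gene, from 10966 to 9.53; the other 8 lowest were introns or reading frames within COX1 and COB. Ribosomal protein genes were lower in 133 of 137, with a relative median of -2.80 (percentile 0). Glycolysis genes were lower in 16 of 17 (relative median -1.51, percentile 0.02), among them FBA1 (1882 to 20.4) and TDH3 (493 to 30.0). Heat shock genes were lower in 11 of 13 (relative median -1.41 with an interval of -3.06 to 0.0029, percentile 0.75), among them SSE1 (555 to 13.7). Mitochondrial ribosomal protein genes were lower in 45 and higher in 2 of 56 (relative median -1.07, percentile 0.33), among them MRPS35 (164 to 1.75). Galactose genes were higher in 5 and lower in 0 of 6 (relative median 3.61, percentile 99.6); GAL1 rose from 36.7 to 426. Meiosis genes were higher in 7 and lower in 4 of 17 (relative median 1.20, percentile 99.7), including IME4, the gene of the RNA methyltransferase of early meiosis (1.32 to 37.0), and SMK1 (4.30 to 78.0). COS genes were higher in 4 and lower in 0 of 7 (percentile 99.8), but COS1, COS7 and COS8 were below the pseudocount in xrn1 and could not be counted as lower. Hexose transporter genes were higher in 4 and lower in 0 of 7 (percentile 96.1), among them HXT2 (266 to 1335). RNA decay genes were lower in 14 and higher in 0 of 20, with PAT1 going from 130 to 7.47, and all 8 histone genes were lower, HTB1 from 127 to 8.69. Phosphate genes were higher in 2 and lower in 5 of 11, with PHO3, an acid phosphatase gene, rising from 201 to 1217 and PHO81 falling from 354 to 37.0, and mating genes were higher in 2 and lower in 4 of 8. RNA decay genes lay at percentile 2.83, histone genes at 30.6, phosphate genes at 31.2 and mating genes at 80.8. R0040C went from 1950 to 0 reads (at least 8530-fold lower) and R0030W from 423 to 0 reads (at least 1851-fold lower), while R0010W and R0020C had 1 read each in xrn1 RNAi. With a pseudocount of 31.8 the relative medians were -1.80 for ribosomal protein, -0.45 for mitochondrial ribosomal protein, 2.04 for galactose and 0.69 for meiosis genes. With only genes of value 31.8 or more that of meiosis genes was 3.11, and that of heat shock genes was -2.45 with a pseudocount of 0.318 and -2.28 with size factors.

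Across all genes, 835 were higher and 3161 lower of 5445; the numbers were 1187 and 2584 when each library was divided by its sum, and 1831 and 1782 with size factors. The comparisons in cells with and without XRN1 share no library. Of 5385 genes counted in both, 534 were higher in both, against 127 for independent lists, and 2632 were lower in both, against 1874. Across these genes, which are not independent replicates, Pearson's r of the log2 differences was 0.77 and Spearman's rho 0.75.

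**Figure D2:**
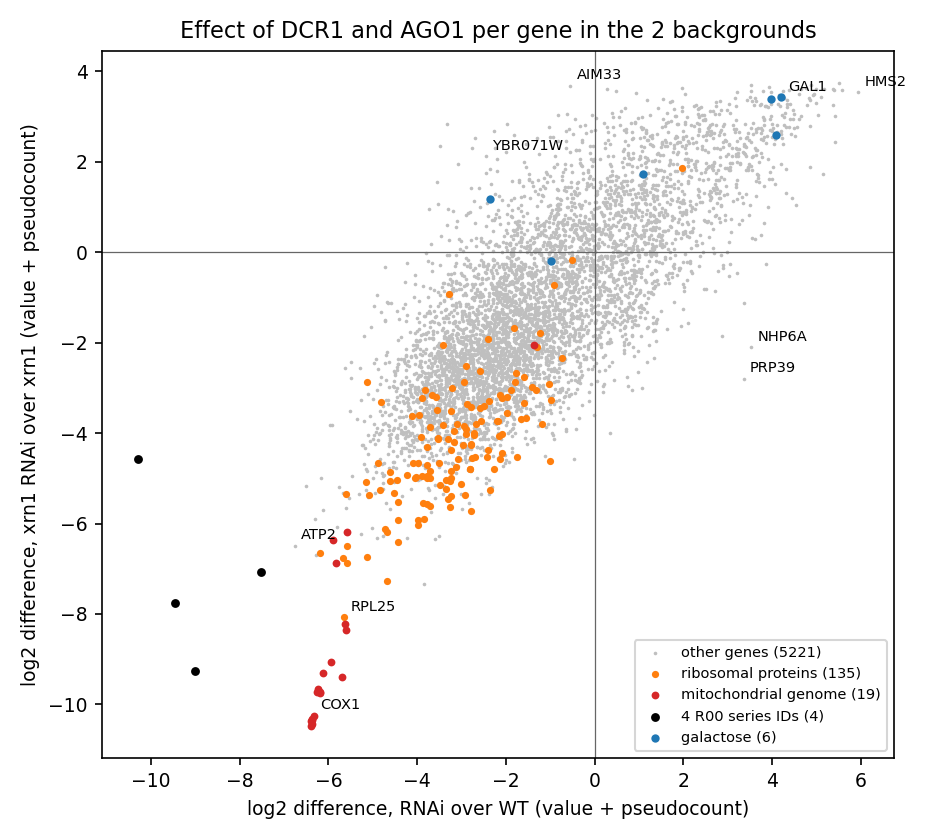
Log2 difference of each gene (value plus pseudocount) on addition of DCR1 and AGO1, in cells with XRN1 (horizontal) and without it (vertical); each point is 1 gene counted in both comparisons. Ribosomal protein and mitochondrial genes lie low on both axes, GAL1 and HMS2 high on both, and PRP39 and NHP6A lie high on one and low on the other.

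Deletion of XRN1 in cells with DCR1 and AGO1 (xrn1 RNAi over RNAi) addressed which small RNAs of cells with the rebuilt pathway differ when the exonuclease is missing. PRP38, a splicing factor gene, rose from 22.9 to 812 (35.5-fold, interval 28.2 to 45.4) and AIM33 from 50.8 to 1377 (27.1-fold, 23.2 to 31.9). POP4, an RNase P and MRP subunit gene, rose from 4.13 to 188, RPB5, an RNA polymerase subunit gene, from 4.45 to 194, and EXG1, a cell wall glucanase gene, from 7.62 to 274, each from 13 to 24 reads in RNAi. The other 5 highest were YLR297W, YBR071W, YOR062C, the mRNA export gene MTR2 and GCV3. PRP39, another splicing factor gene, fell from 716 to 6.02 (119-fold, 94.98 to 151). FRE5 fell from 2770 to 168, the chromatin protein gene NHP6A from 344 to 23.0, and RFC1, a replication factor gene, from 139 to 9.38. The others among the 10 lowest were CRR1, MGA1, DUR12, PET122, LPX1 and SMK1.

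Histone genes were higher in 6 of 6 counted (relative median 0.88, percentile 96.4). HHT1 rose from 2.54 to 41.6 and HHT2 from 16.2 to 96.6. Of the 8 histone genes 12.5% reached the pseudocount in RNAi and 75% in xrn1 RNAi. All those counted except HHT2 passed only through xrn1 RNAi, so they could not be counted as lower. HHF1 and HHF2 were below the pseudocount in both libraries and were not counted (log2 differences of 0.44 and 0.56). Mitochondrial genes were lower in 16 of 16, with COX1 going from 407 to 49.2, and their relative median was -3.24 (percentile 0). Meiosis genes were lower in 4 and higher in 1 of 14 (relative median -0.81, percentile 0.66). Galactose genes were lower in 3 and higher in 0 of 6 (relative median -1.45, percentile 1.65), with GAL1 going from 1607 to 426. The intervals of these 2 medians, -2.04 to 0.29 and -2.46 to 0.27, crossed the nuclear median. The remaining lists lay between percentiles 4.20 and 89.6: ribosomal protein genes were higher in 21 and lower in 1 of 110 (relative median -0.22, and 0.80 with a filter at 10 times the pseudocount), mitochondrial ribosomal protein genes higher in 18 and lower in 0 of 47, glycolysis genes higher in 1 and lower in 5 of 16, heat shock genes higher in 4 and lower in 4 of 12, and RNA decay genes higher in 6 and lower in 4 of 21, 1 of them the deleted gene XRN1 (relative median -0.16, and 0.04 with size factors). Phosphate genes were higher in 2 and lower in 1 of 11, mating genes higher in 2 and lower in 3 of 8, COS genes higher in 1 of 7, and hexose transporter genes higher in 3 of 7. PGI1, a glycolysis gene, went from 311 to 44.7, the chaperone gene SSA1 from 71.5 to 4.27 and HXT2 from 180 to 1335. With a pseudocount of 31.8 the relative medians were 0.13 for histone, -1.29 for mitochondrial, -0.23 for meiosis and -0.79 for galactose genes, and histone genes had 1.93 with a pseudocount of 0.318 and 1.63 with size factors. With only genes of value 31.8 or more the median of meiosis genes was -1.52. Across all genes 1681 were higher and 599 lower of 5084, against 1133 and 1310 with size factors and 592 and 344 with a pseudocount of 31.8, and 941 were higher among genes of value 31.8 or more.

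Deletion of XRN1 in cells without DCR1 and AGO1 (xrn1 over WT) gave higher small RNA values for most ribosomal protein genes. The median of a list of 20 meiosis genes was lower. Ribosomal protein genes were higher in 107 and lower in 0 of 137, with a relative median of 0.999 (percentile 100); RPL10 rose from 329 to 2386 (7.25-fold, interval 6.49 to 8.12), RPL3 from 302 to 2223 and RPL22B from 34 to 471. Glycolysis genes were higher in 14 and lower in 0 of 17 (relative median 1.48, percentile 100), among them TDH2 (9 to 57.8). Histone genes were higher in 6 and lower in 0 of 8 (percentile 99.2), among them HHT2 (15 to 202). Meiosis genes were lower in 12 and higher in 1 of 20 (relative median -1.82, percentile 0), with SPR3 going from 77 to 2.31 and SPO13 from 26 to 0 reads, at least 26.2-fold lower. The 343 genes directly annotated to meiosis or sporulation, a set added after the data were seen, had median values per kb of coding length of 32.2 in WT and 33.3 in xrn1, against 37.1 and 53.7 for nuclear genes. With a pseudocount of 31.8 the relative median was -0.92 for the meiosis list and -0.80 for galactose genes.

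The largest rises were those of HSP12, a heat shock gene (2 to 124), SPL2, of the phosphate response (8 to 232), the cell wall genes CWP1 (15 to 293) and PIR1 (10 to 191), NOG2, a ribosome assembly gene (204 to 3088), MBF1 (71 to 1084), ZEO1 (66 to 986), INH1 (5 to 110), SPO24 and DRE2. NOG2 holds the small nucleolar RNA gene SNR191 on the same strand, and reads of that RNA cannot be told apart from its own. R0010W went from 4351 to 73.7 (59.1-fold lower, 51.6 to 67.9). The largest falls, beyond XRN1 and R0010W, were those of YBL044W (114 to 0.991, 3 reads), the sporulation gene SPO19 (302 to 8.59), YJL043W, YFL040W, the cell wall gene TIR3, the gluconeogenesis gene FBP1 (75 to 1.32), the spore membrane gene SMA2 and GAT4. Galactose genes were lower in 4 and higher in 0 of 7 (relative median -1.64, percentile 0.20), among them GAL2 (31 to 1.98). Mitochondrial genes were higher in 5 and lower in 0 of 19 (percentile 88.1). Heat shock genes were higher in 6 of 13, including HSP82 (39 to 259), RNA decay genes higher in 10 and lower in 2 of 21 (the deleted gene XRN1 and PAP2), phosphate genes higher in 6 of 11 and mitochondrial ribosomal protein genes higher in 25 of 56. Mating genes were higher in 2 and lower in 2 of 8, COS genes lower in 2 of 5 and hexose transporter genes lower in 3 of 8. These 7 lists lay between percentiles 5.22 and 95.9.

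Across all genes 1831 were higher and 545 lower of 5507. The split depended on the scaling, with 996 higher and 1075 lower when each library was divided by its sum and 1132 and 954 with size factors, and a pseudocount of 31.8 gave 937 and 224. The deletion comparisons with and without DCR1 and AGO1 share no library, and 794 genes of 5052 were higher in both, against 556 for independent lists, and 100 lower in both, against 51.4. Pearson's r across these genes was 0.33 and Spearman's rho 0.32.

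**Figure D3:**
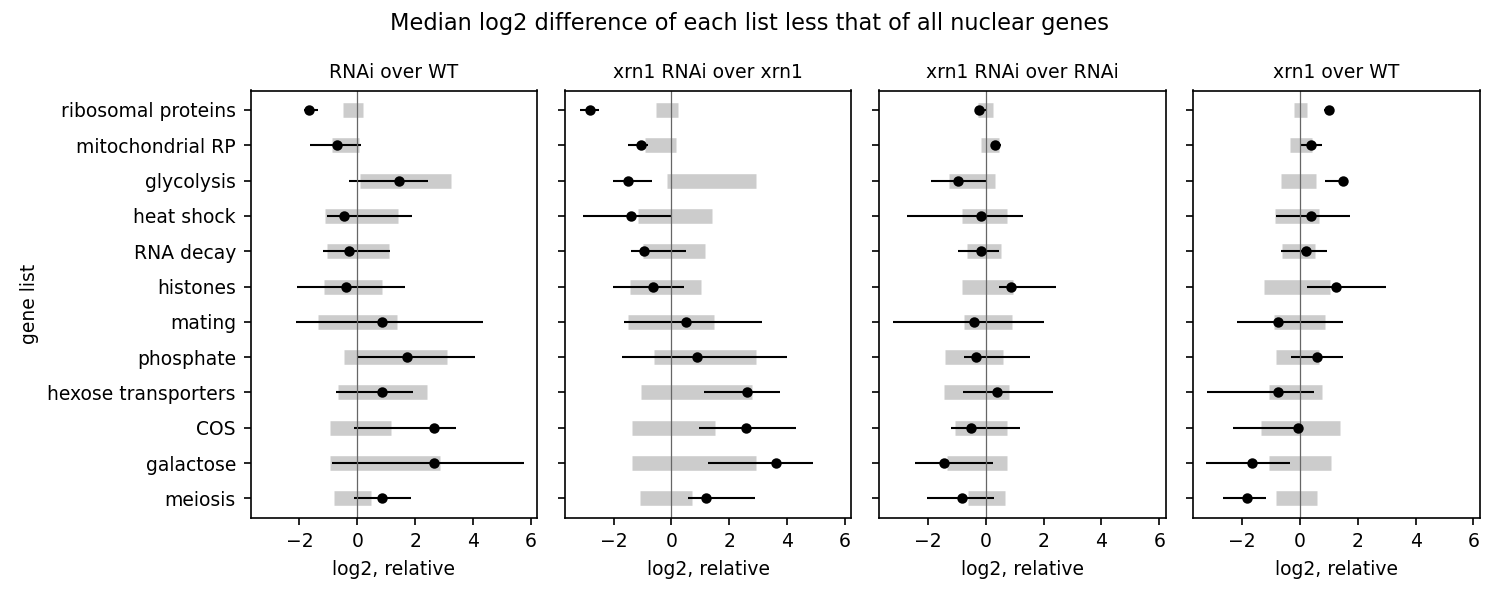
Median log2 difference of 12 gene lists less that of all nuclear genes (horizontal) in the 4 comparisons; points are medians, black bars their 95% binomial intervals and grey bars the central 95% of 10000 random lists matched on mean value. Ribosomal protein genes lie at -1.68 and -2.80 on addition of DCR1 and AGO1 and at 0.999 on deletion of XRN1 alone, and meiosis genes lie at -1.82 in the last.

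The difference between the deletion effects with and without DCR1 and AGO1 was taken per gene as a difference of log2 differences. Among the genes named above it was -6.16 for PRP39, -5.62 for NHP6A, 5.84 for FBP1 and 4.58 for YBR071W. The value for COX1 was negative, as COX1 went from 32851 to 63612 without the rebuilt pathway and from 407 to 49.2 with it. Over all genes 1287 of 5539 had a difference of 1 or more and 1352 of -1 or less; dividing by the sum gave 1958 and 773, and a pseudocount of 31.8 gave 557 and 887. None of these differences was tested.

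Genes that overlap another listed gene by 50 or more bases on the opposite strand can give double-stranded RNA where both are transcribed. There were 29 such genes in 15 pairs. On addition of DCR1 and AGO1 their relative median was 0.89 in cells with XRN1 (4 higher and 10 lower of 23, percentile 99.5) and 1.21 in cells without it (6 higher and 10 lower of 22, percentile 99.9). On deletion of XRN1 it was -1.06 without DCR1 and AGO1 (percentile 0.09) and -0.18 with them (percentile 15.3). The intervals of these medians were -0.66 to 1.30, -0.85 to 2.56, -2.36 to 0.34 and -2.02 to 0.90. Each ran from below to above the nuclear median, so the direction is uncertain. In the same order, a pseudocount of 31.8 gave 0.37, 0.63, -0.44 and -0.0768, genes of value 31.8 or more gave 1.46, 0.34, -0.43 and -1.81, and an overlap of 1 or more bases gave 2.13 for the second, -0.0155 for the third and 0.12 for the last. The pair with the highest lower member in xrn1 RNAi was YJR079W and AIM24, with values of 53.2 and 73.7 there, 6.61 and 80.6 in xrn1, 6.67 and 14.6 in RNAi, and 21 and 130 in WT. VPS5 and VAM10 had 120 and 14.1 in xrn1 RNAi, and HPA3 and YEL067C 14.6 and 54.9. MTO1 and YGL235W had 55.3 and 8.77 there and 172 and 56.5 in RNAi. The remaining 4 pairs named were FYV5 with ADF1, IMO32 with NAG1, BUD25 with FAA2 and YDR114C with MRX14. Whether the counting used the strand of the reads is not given in the sources used here, so reads of the members of a pair cannot be assigned to one strand.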

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

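The tests in this part, other than the log2 differences, were chosen after the values they bear on had been seen. Of 126 named genes examined, 13 had effects of DCR1 and AGO1 of 1 or more in size and in opposite directions in cells with and without XRN1, and 11 had such opposite effects of the XRN1 deletion. The named genes were chosen largely for extreme differences. Of all 5385 genes counted in both backgrounds, 37 were higher with XRN1 and lower without it, and 65 the reverse. For the deletion, 75 of 5052 were higher with DCR1 and AGO1 and lower without them, and 66 the reverse. Some flagged genes had few reads: values in xrn1, where 1 read was worth 0.330, were 0.330 for VAM10, 0 for SPO13 and 1.98 for GAL2. With size factors 10 of the 13 and 11 of the 11 kept opposite signs, and YOR062C, YJR079W and HPA3 were higher with DCR1 and AGO1 in both backgrounds. The differences between backgrounds were not tested, since each effect rests on 1 library against 1.

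For the addition of DCR1 and AGO1, the log2 difference between the effects without and with XRN1 was -6.16 for PRP39, which was higher in RNAi than in WT (3.36) and lower in xrn1 RNAi than in xrn1 (-2.80). It was -5.62 for NHP6A, -4.08 for the glycolysis gene PGI1 and -2.33 for HPA3, which went the same way. The other 9 genes were lower with the pathway in cells with XRN1 and higher in cells without it: 5.84 for FBP1, 4.58 for YBR071W, 4.55 for VAM10, 4.04 for SPO13, 3.82 for YJR079W, 3.54 for GAL2, 3.51 for POP4, 3.25 for TIR3 and 2.35 for YOR062C. For the XRN1 deletion, the same difference applies to NHP6A, FBP1, PGI1 and YJR079W. The mitochondrial intron genes AI1 (-3.95), BI2 (-3.53) and BI3 (-3.47), the chaperone gene SSA1 (-4.34) and the glycolysis genes PDC1 (-3.59) and TDH3 (-3.48) were higher on deletion without the pathway and lower with it, and RSB1 (3.34) went the other way.

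Most genes had lower values in the libraries with DCR1 and AGO1. The scaling of the libraries moves every gene of a library by 1 factor, and cannot give the unequal fall: ribosomal protein genes lay -1.68 from the nuclear median in RNAi over WT and -2.80 in xrn1 RNAi over xrn1, outside the central 95% of random lists (-0.51 to 0.21 and -0.53 to 0.23). Unequal read numbers stay open for the shared fall. With every library thinned to 627607 reads the nuclear medians stayed at -1.56 and -1.46. Thinning keeps the expected ratios, so this outcome was fixed in advance. It cannot tell whether depth entered the rule of scaling. The shared part of the fall cannot be told apart from the scaling, because size factors set the nuclear median near 0 by construction (-0.0417). That small RNAs made by the pathway take a part of each library may leave fewer reads for fragments of abundant RNAs, and this stays open as untested.

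Of the 20 meiosis genes of the list, 12 were 2-fold or more lower in xrn1 than in WT, 1 was higher and 7 were neither. An even background along genes in the WT library stays open: WT reads per kb of coding length in the list were 1.29 times those of the 526 other genes lowest in xrn1, with a bootstrap interval of 0.654 to 1.87 that is too wide to decide. The log2 ratio of the upper to the lower quartile of WT reads per kb in the list was 1.70, which decides nothing, since it was 1.54 for all nuclear genes. An effect of the XRN1 deletion itself stays open too. In xrn1 RNAi over RNAi the list lay at percentile 0.66, but its relative median of -0.81 had an interval of -2.04 to 0.29, and 9 of 14 members differed by less than 2-fold.

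The identifiers R0010W, R0020C, R0030W and R0040C, which the systematic naming scheme gives to the 2-micron plasmid (an assignment that rests on the names alone), had 8779 reads together in WT and 9519 in xrn1, 1 read in RNAi and 2 in xrn1 RNAi; libraries differ in depth, and on the deposited scale 2 of the 4 were also lower in xrn1 than in WT (relative median -1.57, percentile 0.40). Had they fallen as far as the most reduced of the 74 other genes with 500 or more WT reads, 193 reads would remain in RNAi (BAT1) and 19.9 in xrn1 RNAi (the mitochondrial gene BI2). The identifiers were picked for the lowest differences in RNAi over WT, so that comparison decides nothing about a general fall. In xrn1 RNAi over xrn1, which shares no library with it, the values argue against a fall no larger than that of these 74 genes. Genes with fewer WT reads were left out, and a larger fall particular to these identifiers is not excluded. A loss of the DNA that carries them, in the DCR1 AGO1 strains, is consistent with 1 and 2 stray reads, and may be a property of the strains rather than of the pathway. No strain history was used here, so a selection, a cross or a strain background that removed the plasmid cannot be separated from the pathway.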

How the results depend on the processing

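The comparisons rest on 1 library each, so that no setting can speak to replicate error, and most counts that moved did so with size factors or a pseudocount of 31.8. Of the counts of higher and lower genes under the other settings, 41 stayed within 1.5 times and 19 did not. All counts with no filter, or with a pseudocount of 0.318, stayed. In the 4 comparisons, 2 values below the pseudocount cannot differ 2-fold once it is added. Removing the filter could therefore change no count there, and is no check of them. With size factors RNAi over WT gave 1911 higher and 1833 lower, xrn1 RNAi over xrn1 1831 and 1782, xrn1 over WT 1132 and 954, and xrn1 RNAi over RNAi 1310 lower. Division by the sum gave 996 higher and 1075 lower for xrn1 over WT, and 1958 and 773 for the difference of deletion effects. A pseudocount of 31.8 gave 1898 lower for RNAi over WT, 592 higher and 344 lower for xrn1 RNAi over RNAi, 937 and 224 for xrn1 over WT, and 557 and 887 for the difference. A filter at 10 times the pseudocount gave 941 higher for xrn1 RNAi over RNAi, as fewer genes were counted. Otherwise the cause was not tested.

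Of the relative list medians 198 stayed in their interval, 22 moved out of it and 1 changed sign beyond it. That of ribosomal proteins in xrn1 RNAi over RNAi changed sign, to 0.80, with the filter at 10 times the pseudocount (interval -0.45 to 1.48). With a pseudocount of 0.318, ribosomal protein medians were -2.06 and -3.21 in RNAi over WT and xrn1 RNAi over xrn1, and with 31.8 -0.91 and -1.80, and 0.81 in xrn1 over WT. Mitochondrial ribosomal proteins had -2.08 (0.318) and -1.90 (filter) in RNAi over WT, -1.58 (0.318) and -0.45 (31.8) in xrn1 RNAi over xrn1, and 0.66, 0.0339, 0.96 and 0.60 in xrn1 RNAi over RNAi (0.318, 31.8, filter, size factors). Mitochondrial genome genes had -6.44 (31.8) in xrn1 RNAi over xrn1, -3.89 (0.318) and -1.29 (31.8) in xrn1 RNAi over RNAi, and 0.52 (31.8) in xrn1 over WT. With the filter, genes with an antisense partner had 1.46 in RNAi over WT and meiosis genes 1.95 there and 3.11 in xrn1 RNAi over xrn1. With a pseudocount of 31.8, meiosis genes had -0.92 in xrn1 over WT and histones 0.13 in xrn1 RNAi over RNAi. The cause was not tested.

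For 128 differences of single genes, 213 values stayed in their counting interval and 299 moved out of it under both pseudocounts and both scalings. None of these 128 changed sign, but with size factors some smaller differences did, among them those of YOR062C (to 0.35) and YJR079W (to 0.23) in RNAi over WT and of HPA3 (to 0.20) in xrn1 RNAi over xrn1. Scaling by snoRNAs was not run, as the table lists none. Depth limits the genes with 1 to 20 reads, of which there were 1227 in WT, 1983 in RNAi, 284 in xrn1 and 341 in xrn1 RNAi.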

Other observations

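All tests in this part, and the annotation terms named in it, were chosen after the values had been seen. Of 226 directly annotated gene ontology terms with 20 to 300 genes, 5.65 would lie beyond either end of the central 95% of 1000 random lists by chance. On addition of DCR1 and AGO1, 40 terms lay below it in RNAi over WT and 52 in xrn1 RNAi over xrn1, while 9 and 5 lay above it, so that the high terms are few against chance. Genes of the cytosolic small ribosomal subunit were lower in 37 and higher in 0 of 39 in both (relative medians -1.69 and -2.91). Genes for maturation of the small subunit rRNA were lower in 58 and higher in 0 of 64 (-1.48), and lower in 56 and higher in 0 of 64 (-2.02). RNA helicase genes were lower in 18 and higher in 1 of 21 (-2.05), and lower in 19 and higher in 0 of 22 (-2.05). Among the high terms, genes of the cell periphery had relative medians of 1.02 (percentile 99.9) and 0.89 (percentile 99.7), vacuole genes 0.79 (99.8) and 1.10 (100), chromatin genes 1.02 (99.9) and 0.51 (85.7), genes for sequence-specific DNA binding 0.92 (100) and 0.62 (97.3), and transmembrane transport genes 0.66 (47.2) and 1.44 (98.0), in RNAi over WT and xrn1 RNAi over xrn1. In the same comparisons, related terms did not all lie high. DNA binding genes had -1.18 (percentile 0) and -0.79 (1.7), and chromatin binding genes -0.20 (24.5) and -0.51 (2.6). Vacuole membrane genes had 0.57 (86.1) and 0.39 (64.55). With XRN1 deleted and no rebuilt pathway, 38 terms lay above and 19 below. There, 24 of 48 ascospore wall genes were lower and 4 higher (-1.51, percentile 0), and 80 of 105 cytoplasmic translation genes were higher and 0 lower (0.92, percentile 100).

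A hypothesis is that convergent genes whose ends lie close together give small RNAs through the paired ends of their transcripts. Among convergent coding neighbours in the reference, 355 genes with a partner less than 100 bases away had a median log2 difference of -1.08 in RNAi over WT (interval -1.44 to -0.88), against -1.88 for 1448 genes with a partner at 200 or more and under 1000 bases. In xrn1 RNAi over xrn1 the medians were -0.56 (357 genes) and -1.91 (1446 genes). Both groups of close genes lay at percentile 100 of 10000 random lists of convergent genes matched on mean value, in broader bins than those of the gene lists. Random lists drew single genes, while both members of a close pair entered, so neighbours that can share reads counted as independent. No lower limit was set on the distance, so pairs whose ends overlap count as close. Of the close genes 16.9% were 2-fold or more higher in RNAi over WT, against 11.3% at 200 or more bases, and 21.8% against 10.4% in xrn1 RNAi over xrn1. At 100 to under 200 bases the shares were 10.7% and 12.5%, and the medians -1.78 and -1.39. In RNAi over WT the share therefore did not fall steadily with distance. Over all genes, 833 of 5479 and 835 of 5445 were higher, and the nuclear medians were -1.56 and -1.46. Genes at 200 or more bases lay below these medians, which makes up part of the contrast. The higher medians of close genes go with the hypothesis, although most close genes were not higher. Reads of a neighbour that runs into the gene could also raise close pairs, since the treatment of strand is not known.

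A second hypothesis is that genes under an antisense RNA that the reference annotates give small RNAs. The reference lists 7 such RNAs over 8 coding genes: GAL10, TAT1, ZIP2, IME4, SPS100, TUB3, PHO84 and GAL4. In RNAi over WT 4 of the 8 were higher (relative median 2.19, percentile 93.8), which does not decide the matter, and in xrn1 RNAi over xrn1 6 of the 8 (3.26, percentile 99.5 of 10000 random lists), which is consistent with it in that background. TAT1 rose from 271 to 4328 in RNAi and GAL4, the galactose regulator gene, from 55 to 910, while TUB3 fell from 67 to 5.40.

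The edgeR fit, added after the data were seen, called 450 genes higher and 2584 lower with DCR1 and AGO1 at a Benjamini-Hochberg FDR of 0.05, and 151 higher and 18 lower with XRN1 deleted, of 5539. With TMM scaling the numbers were 1138 and 1012, and 25 and 21. The fit compares these 4 libraries and treats any difference between backgrounds as error. In data simulated at its own dispersion of 0.254 it recovered 36 of 200 genes changed 8-fold by DCR1 and AGO1, so a gene it did not call is not shown to be unchanged.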
